A study of Homo sapiens with 9 samples.

How the data were processed

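RNA was measured by sequencing of poly(A)-selected libraries from HEK293T cells, a human embryonic kidney line, in 9 samples that fall into 3 groups of 3. The groups are cells labelled EV, cells with stable expression of the fusion protein NUP98-PHF23 carrying a GFP-FLAG tag, and cells with the FA form of that fusion, in which phenylalanines of the NUP98 phenylalanine-glycine repeats are replaced by alanine. Groups and replicate numbers were taken from the sample titles. The design text names the parent cells as HEK293FT and the sample labels as HEK293T. A further mutant in the PHD finger of PHF23 that the design text names was not analysed here.

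The authors deposited 1 table of 21502 rows and 9 columns of FPKM (fragments scaled by transcript length and by mapped fragments), with 1 column per sample and 0 columns of other samples. Expression was estimated with RSEM on hg38 and DESeq was also used, per the submitters' processing notes, which give no versions. The aligner and the annotation are not given in the sources used here. RSEM shares reads that match several genes or transcripts between them, so the values of pseudogenes, histone genes and paralogs such as F8A2 and F8A3 are uncertain, as are those of small RNAs shorter than a sequenced fragment. Whether reads were counted by strand is not given in the sources used here, so overlapping antisense genes cannot be separated. Of the rows, 23 carry names turned into dates and 4 share a name with another row. By symbol 16239 rows, and by an older symbol another 765, were matched to GENCODE release 29 on GRCh38, 17004 in all; coordinates below are 1-based and come from that match.

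Total counts are not in the table, so depth was read from the low values. For 1564 rows with a mean FPKM under 2 whose genes have 1 transcript, 95.3% were whole multiples of what 1 fragment is worth in every library, within a tolerance of 0.02 of a fragment. The share was 9.56% for 1977 low rows of genes with 5 or more transcripts and 30.4% for all rows, so counts were not recovered for a count model. The step sizes imply 2.00e+07, 2.05e+07 and 2.01e+07 fragments in the EV libraries, 1.88e+07, 1.93e+07 and 1.87e+07 in the FA libraries and 1.67e+07, 1.76e+07 and 1.84e+07 in the NUP98-PHF23 libraries. One fragment on 1 kb of transcript is worth between 0.0489 and 0.0600 FPKM. The FPKM columns sum to 1.60e+06 to 1.62e+06 in EV, 1.68e+06 to 1.69e+06 in FA and 1.79e+06 to 1.87e+06 in NUP98-PHF23; FPKM columns do not share 1 total.

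Values were taken to log2(FPKM + 1), and rows with an FPKM of 1 or more in at least 3 of the 9 samples were kept, 15458 in all. One linear model over the 3 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options), which leaves 6 residual degrees of freedom. Each contrast was tested with limma's moderated statistic, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every fold change below is on the log2(FPKM + 1) scale, which understates changes of weakly expressed genes; ± is the SE for a log2 fold change and the SD over 3 libraries for an FPKM. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, and technical spread was not separated.

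A set of 33 gene lists had been fixed before the data were examined, as had the main test, the alternatives below unless said otherwise, and the rule for naming genes. Of 1003 list members 850 were found in the table. The 30 lists with 3 or more tested genes were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. The named genes are, per contrast, the 10 largest rises and the 10 largest falls among called genes with a mean FPKM of 2 or more in the higher group and no overlap between the 2 groups' libraries, together with NUP98, PHF23 and up to 4 members with the smallest p from each list. Markers of blood, neuronal, epithelial, fibroblast and endothelial cells were among the lists.

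The fit was tested on simulated data for the contrast of NUP98-PHF23 with EV over 15458 genes, with 50 genes changed at each fold. It called 14% of genes changed 1.25-fold, 44% at 1.5-fold, 78% at 2-fold and 88% at 4-fold, 100% of them in the right direction, and 9 unchanged genes, 7.44% of its calls. With no change simulated, it called 0 genes for FA against EV. In the same data camera found a list of 30 genes shifted by 0.3, and 1.5% of 200 unshifted lists fell under 0.05 before adjustment. The noise was drawn separately for each gene and the lists were random. This share therefore does not apply to lists of genes that vary together.

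Libraries of a group were compared before averaging. Pearson correlations of log2 values were 0.983 to 0.985 within groups and 0.969 to 0.982 between them, and no 2 libraries held identical values, so all 9 were kept as separate samples. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of 5 or more, rescaling of each column to the same sum (TPM), quantile normalization, median ratio scaling, fits of the 6 compared samples only, a replicate block, eBayes without trend or robust, a 2-fold minimum and leaving out each library. To avoid shared controls, the fold changes of the 2 fusion lines were also taken against separate EV libraries, a step chosen after the result was seen. Added after seeing the data were fits without chromosome 8, with the median of each 10 Mb window removed, with trends on transcript length or GC content removed, and without genes shorter than 300 bases. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.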

Results

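Expression was compared in 3 groups of 3 libraries from HEK293T cells: cells labelled EV, cells with the intact NUP98-PHF23 fusion and cells with its FA form. NUP98-PHF23 joins the phenylalanine-glycine repeats of the nucleoporin NUP98 to the part of PHF23 that holds a PHD finger, a module that reads histone methylation. The lines can also differ in ways other than the fusion, which no test here separates from it. The design asks which of the fusion's effects need the phenylalanines of the repeats. All 9 libraries were of similar depth, with 1.67e+07 to 2.05e+07 fragments implied by the FPKM values, and n = 3 for every mean below.

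Both partner genes of the fusion were far higher in the 2 fusion lines than in EV. NUP98 (chromosome 11, 3671083 to 3797792, GRCh38) stood at 165.9 ± 9.75 FPKM in EV, 508.7 ± 15.3 in NUP98-PHF23 and 582.4 ± 6.72 in FA. PHF23 (chromosome 17, 7235028 to 7239722) stood at 65.95 ± 0.923, 301.4 ± 4.96 and 424.5 ± 4.97 FPKM. Relative to EV, log2 fold changes were 1.61 ± 0.04 for NUP98 and 2.18 ± 0.03 for PHF23 in NUP98-PHF23 cells, and 1.81 ± 0.04 and 2.67 ± 0.03 in FA cells (limma, adjusted p = 3.13e-07, 1.13e-08, 8.92e-07 and 2.23e-09). The FA line carried more of both than the intact line, by a log2 difference of -0.20 ± 0.04 for NUP98 (adjusted p = 0.00899, lost at -0.12 and adjusted p = 0.11 with window medians removed) and -0.49 ± 0.03 for PHF23 (adjusted p = 6.77e-06) in NUP98-PHF23 minus FA. Reads of the transgene and of the endogenous genes are added together in these values, and how the alanine codons affected alignment to NUP98 was not tested. Transgene reads need not follow the window of the endogenous gene, so removal of its median cannot decide whether NUP98 differed between the fusion lines.

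**Figure D1:**
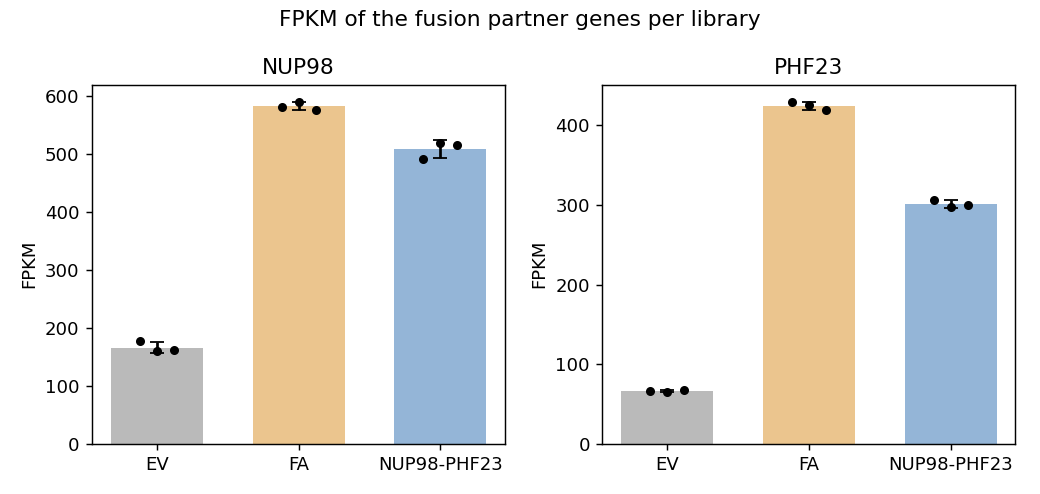
FPKM of NUP98 and PHF23 in each of the 9 libraries (points), with the mean of each group (bars) and the SD over 3 libraries (error bars); the vertical axes start at 0. Both genes were lowest in EV, at 165.9 and 65.95 FPKM on average, and highest in FA, at 582.4 and 424.5.

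The intact fusion was compared with EV to find the genes that differ with it. Several genes that were almost silent in EV were abundant in NUP98-PHF23 cells. KISS1R, the kisspeptin receptor (chromosome 19, 917287 to 921015), went from 0.0852 ± 0.0562 to 105 ± 7.80 FPKM (log2 fold change 6.62 ± 0.10), and NGFR, a neurotrophin receptor (chromosome 17, 49495293 to 49515017), from 0.224 ± 0.0369 to 35.0 ± 1.02 (4.88 ± 0.08). The Wnt-inactivating enzyme NOTUM rose from 0.422 ± 0.281 to 28.7 ± 1.29 FPKM (4.40 ± 0.15), the Notch-regulated repressor HES7 from 2.15 ± 0.533 to 55.0 ± 0.690 (4.16 ± 0.13) and CASKIN1 from 2.94 ± 3.09 to 57.1 ± 24.3 (4.06 ± 0.56). In the other direction CCND1, which encodes cyclin D1 (chromosome 11, 69641087 to 69654474), fell from 60.02 ± 6.06 to 2.44 ± 0.540 FPKM (-4.16 ± 0.14). The peroxidasin gene PXDN fell from 13.3 ± 1.17 to 0.0583 ± 0.0353 (-3.75 ± 0.13).

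PRAC1, which lies beside HOXB13, and the long noncoding RNA AC005256.1 were listed at 0 in all EV libraries and reached 25.5 ± 1.22 and 33.2 ± 3.57 FPKM with the intact fusion. MGST1, a microsomal glutathione transferase, stood at 17.9 ± 11.8 FPKM in EV and was listed at 0 in all NUP98-PHF23 libraries. The noncoding CTD-2319I12.1 rose (log2 fold change 4.18 ± 0.34), and RAB3IL1 (-4.04 ± 0.86) and RP11-150O12.1 (-3.62 ± 0.58) fell. The pseudogenes TMSB4XP6, higher, and STK19P, lower, and the microRNA gene MIR3665, lower, also met the naming rule, but their short or duplicated sequence makes their values uncertain. The calls of AC012360.2, SNORA69, RP11-536C10.19 and AL592188.6 ended when single libraries were left out, with adjusted p up to 0.0967, 0.0815, 0.0749 and 0.0734. At the extremes, 13 genes went from under 0.5 FPKM in every EV library to 5 or more in every NUP98-PHF23 library, among them CLDN6, ONECUT3, BHLHE23, CACNA1G and MAGEA11, and 9 went the other way, including TMEM47. These 6 names were picked after their values were seen.

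Among HOX genes, which encode transcription factors of body axis patterning, only the HOXB cluster moved as a whole. All 9 tested HOXB genes rose, 9 also when adjusted over the list alone, with a median log2 fold change of 1.04 (camera adjusted p = 1.73e-06, and adjusted p = 0.0488 with an estimated correlation). HOXB9 went from 79.2 ± 0.852 to 166.9 ± 2.85 FPKM and HOXB13 from 6.03 ± 0.339 to 13.5 ± 0.930. Of 7 HOXD genes 4 fell and 0 rose, also when adjusted over the list alone, with HOXD10 at -0.87 ± 0.07 and HOXD11 at -0.84 ± 0.07 (camera adjusted p = 0.0191, lost at adjusted p = 0.129 with an estimated correlation and at 0.0826 with window medians removed). HOXA genes split, 3 up and 3 down of 11 on either adjustment: HOXA13 rose from 8.63 ± 0.653 to 23.65 ± 0.450 FPKM, and HOXA9 fell from 94.3 ± 5.80 to 56.1 ± 0.211 (camera adjusted p = 0.831). Of 7 HOXC genes 3 rose, led by HOXC11 (1.16 ± 0.09), and 1, HOXC4 (-0.56 ± 0.06), fell, also over the list alone (adjusted p = 0.254).

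**Figure D2:**
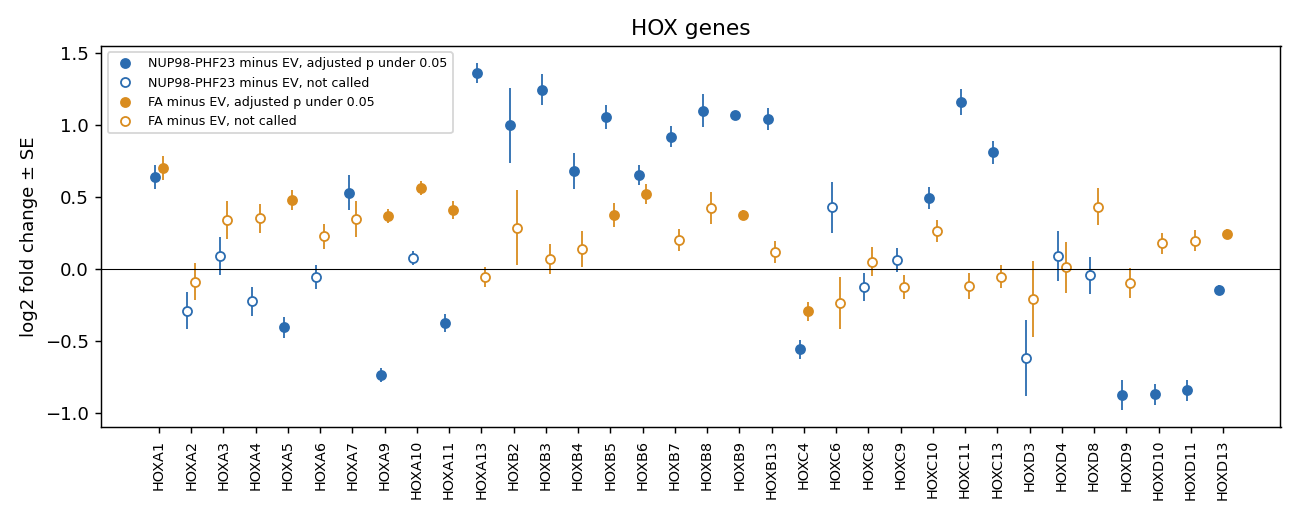
Log2 fold changes against EV of every tested HOX gene (vertical axis; bars are the SE) for NUP98-PHF23 (blue) and FA (orange), with filled points for adjusted p under 0.05. The 9 HOXB genes lie above 0 in NUP98-PHF23, with a median of 1.04, against 0.29 in FA, and 4 of 7 HOXD genes were called lower in NUP98-PHF23.

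Chaperone and p53 target genes were lower with the intact fusion. Of 17 heat shock response genes 12 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.45, camera adjusted p = 1.285e-07, and adjusted p = 0.0451 with an estimated correlation). HSPA1B, an inducible HSP70 gene, fell from 1658 ± 12.5 to 854.2 ± 14.1 FPKM, and HSPD1, the mitochondrial chaperonin, from 1059 ± 14.7 to 549.1 ± 8.88. Of 24 p53 target genes 14 fell and 3 rose (15 and 3 over the list alone; median -0.57, adjusted p = 0.00041, and adjusted p = 0.0473 with an estimated correlation), with PHLDA3 falling from 30.1 ± 2.03 to 5.47 ± 1.22 FPKM and CDKN1A, the cell cycle inhibitor p21, from 26.0 ± 2.24 to 10.5 ± 0.814. Of 22 immediate early genes, which respond within minutes to growth signals, 12 rose and 6 fell (14 and 6 over the list alone; median 0.45, adjusted p = 0.0108, lost at adjusted p = 0.0956 with an estimated correlation). IER2 rose by 1.46 ± 0.06, DUSP1 by 1.52 ± 0.06 and JUNB by 1.54 ± 0.09 on the log2 scale.

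Genes of the translation machinery went opposite ways. Of 76 cytosolic ribosomal protein genes 73 rose and 1 fell, also over the list alone, with a median of 0.46 (camera adjusted p = 6.84e-34, lost at adjusted p = 0.19 with an estimated correlation); RPL4 went from 5119 ± 46.4 to 8296 ± 158 FPKM. Of 35 ribosome biogenesis genes, which act in the nucleolus, 22 fell and 1 rose (23 and 1 over the list alone; median -0.23, adjusted p = 1.285e-07, and adjusted p = 0.0451 with an estimated correlation). NPM1, encoding nucleophosmin, fell by 0.63 ± 0.03 and LYAR by 0.44 ± 0.03. NOP56 and DKC1 were also called lower (-0.68 ± 0.03 and -0.42 ± 0.03), but both lie in windows of chromosomes 20 and X whose genes were lower as a whole, and with the window medians removed their values were 0.0091 and 0.14.

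Energy metabolism genes changed in both directions. Nuclear oxidative phosphorylation genes rose in 29 and fell in 5 of 46 cases (31 and 6 over the list alone; median 0.25, adjusted p = 1.43e-06, lost at adjusted p = 0.323 with an estimated correlation), with COX6A1 at 0.81 ± 0.04. Of the 13 mitochondrially encoded genes 7 fell and 1 rose (8 and 2 over the list alone; median -0.19, adjusted p = 0.0278, lost at adjusted p = 0.66 with an estimated correlation). Of 32 hypoxia and glycolysis genes 14 fell and 4 rose (14 and 6 over the list alone; adjusted p = 0.0338, lost at adjusted p = 0.19 with an estimated correlation and at 0.0614 with window medians removed). Here DDIT4 fell from 29.4 ± 1.04 to 7.11 ± 0.554 FPKM and PFKP from 127.2 ± 4.90 to 44.2 ± 4.28, while the aldolase gene ALDOC rose from 5.66 ± 0.197 to 38.1 ± 1.05 and NDRG1 from 72.0 ± 1.24 to 184.1 ± 8.24. Of 40 DNA replication genes 17 rose and 7 fell (18 and 7 over the list alone; adjusted p = 0.0448, lost at adjusted p = 0.129 with an estimated correlation), with MCM3 and MCM7 both at 0.43 ± 0.03. That call was also lost with the replicate block (adjusted p = 0.0601), with quantile normalization (0.205) and with the length (0.0962) or GC (0.0912) trend removed. Without 1 library, 15 to 18 DNA replication genes were called higher and 4 to 6 lower.

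In total 5999 of 15458 genes, 38.8%, were called between NUP98-PHF23 and EV, 3127 higher and 2872 lower, and 486 and 436 of these changed by 2-fold or more. The libraries of the 2 groups did not overlap for 51.5% of genes, where chance gives 10%. Rescaling to TPM, which lowers the median gene by 0.15, turned the split to 2004 higher and 4961 lower. The median of ribosomal protein genes was 0.28 under TPM and 0.17 with quantile normalization. That of nuclear oxidative phosphorylation genes was 0.07 and 0.12, and that of DNA replication genes 0.0026 and 0.13. In the test with an estimated correlation 4 of the 11 called lists held. The fry test, which does not compare a list with other genes, called 20 of the 30 lists, all 11 among them.

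The FA form was compared with EV to see what remains without the phenylalanines. Fewer genes differed between the FA line and EV, and by less. Among genes above 0 in EV, the largest rises kept in every alternative beside those of PHF23 and NUP98 were those of NEK11, a kinase of the DNA damage response, from 2.61 ± 0.190 to 15.9 ± 3.63 FPKM (log2 fold change 2.20 ± 0.24), and FAAH2, a fatty acid amide hydrolase, from 0.444 ± 0.528 to 4.69 ± 1.22 (2.02 ± 0.28). CCND1 fell from 60.02 ± 6.06 to 6.33 ± 0.821 FPKM (-3.06 ± 0.14), PXDN to 0.731 ± 0.271 (-3.05 ± 0.13), the homeobox gene UNCX from 11.5 ± 0.855 to 0.109 ± 0.1203 (-3.50 ± 0.12), the protease gene BACE2 from 7.48 ± 0.935 to 0.117 ± 0.0587 (-2.92 ± 0.12) and the tropomyosin gene TPM2 from 28.0 ± 0.656 to 3.61 ± 0.161 (-2.66 ± 0.14). MGST1 was listed at 0 in all FA libraries, as in NUP98-PHF23. F8A3 was listed at 0 in EV and reached 7.82 ± 2.59 FPKM in FA, while its near-identical copy F8A2 went from 7.93 ± 1.03 FPKM to being listed at 0, so their reads cannot be told apart securely.

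The other 8 genes that met the naming rule lost their call in at least 1 alternative, each of them without 1 or more single libraries. They were RP11-76H14.2, RP11-809N8.4, RPS20P10, RP11-43A14.1 and RP11-103G8.2, higher, with adjusted p up to 0.1199, 0.0762, 0.0998, 0.0818 and 0.119, and NPM2, AC245884.3 and AC004383.3, lower, with adjusted p up to 0.109, 0.112 and 0.1201.

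Some HOXA and HOXB genes rose modestly in FA cells. Of 11 HOXA genes 5 rose and 0 fell (9 over the list alone; median 0.35, camera adjusted p = 1.36e-05, lost at adjusted p = 0.07035 with an estimated correlation), led by HOXA10, from 59.7 ± 0.937 to 88.8 ± 4.58 FPKM. Of 9 HOXB genes 3 rose (5 over the list alone; median 0.29, adjusted p = 0.00044, lost at 0.0988 with an estimated correlation), with HOXB9 at 0.38 ± 0.03 and HOXB6 at 0.52 ± 0.07. Of 7 HOXD genes 1 rose (2 over the list alone; adjusted p = 0.114), and of 7 HOXC genes 1, HOXC4, fell (1 up and 1 down over the list alone; adjusted p = 0.413). The HOXC4 call was lost in 10 alternatives, at adjusted p up to 0.108.

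Neuronal marker genes fell in FA, 4 of 9 against 1 higher (5 and 1 over the list alone; median -0.39, adjusted p = 0.000159, lost at adjusted p = 0.0988 with an estimated correlation). The neurofilament genes NEFL and NEFM went from 6.72 ± 0.0524 to 1.30 ± 0.0484 and from 60.8 ± 1.78 to 21.4 ± 1.92 FPKM, and STMN2 from 3.15 ± 0.203 to 0.249 ± 0.0776. All 3 lie on chromosome 8, most of whose genes were higher in FA. Extracellular matrix and mesenchymal genes were lower in 3 and higher in 2 of 19 cases (7 and 2 over the list alone; adjusted p = 0.00813, lost at 0.0988 with an estimated correlation), with COL6A1 at -0.60 ± 0.09. Of 57 developmental transcription factors 7 fell and 4 rose (13 and 6 over the list alone; adjusted p = 0.00813, lost at 0.0872 with an estimated correlation, 0.0606 with quantile normalization and 0.059 with the GC trend removed), with HAND1 at -0.74 ± 0.10. Of 14 secreted developmental signals 3 fell and 0 rose (4 over the list alone; adjusted p = 0.041, lost at 0.132 with an estimated correlation), with the BMP antagonist NOG at -0.82 ± 0.10; this call was also lost with the replicate block (0.0663), quantile normalization (0.105), window medians removed (0.0516) and the GC trend removed (0.0722).

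Oxidative phosphorylation genes rose in 23 and fell in 0 of 46 cases in FA (30 over the list alone; median 0.15, adjusted p = 5.29e-17, lost at adjusted p = 0.132 with an estimated correlation). UQCRB, NDUFB9 and COX6C, 3 of its 4 members with the smallest p, lie on chromosome 8. UQCRB and COX6C lost their call with window medians removed (adjusted p = 0.146 and 0.0572). Ribosomal protein genes rose in 37 and fell in 1 of 76 cases (54 and 1 over the list alone; median 0.12, adjusted p = 1.18e-22, lost at adjusted p = 0.263 with an estimated correlation and 0.0584 with quantile normalization), and RPL7 (0.50 ± 0.03) and RPL8 (0.40 ± 0.03) also lie there. RPL7 lost its call with window medians removed (adjusted p = 0.161). Of 24 p53 target genes 2 rose and 0 fell (6 over the list alone; median 0.18, adjusted p = 0.00134, lost at 0.0872 with an estimated correlation). Of 17 heat shock genes 3 rose and 0 fell (5 and 1 over the list alone; median 0.07, adjusted p = 0.00302, lost at 0.125 with an estimated correlation and 0.345 with quantile normalization), HSPH1 by 0.34 ± 0.04. Of 35 mitotic genes 5 rose (6 up and 1 down over the list alone; adjusted p = 0.0467, lost at 0.263 with an estimated correlation, 0.345 with quantile normalization, 0.0516 with window medians removed and 0.286 with the GC trend removed). Among single genes, the glycolytic enzyme gene ALDOA, in a window of chromosome 16 that was lower as a whole, fell from 3406 ± 25.7 to 1567 ± 27.1 FPKM and MYC from 122.0 ± 2.28 to 90.7 ± 2.43.

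The number of called members of these lists changed with single libraries, as counted after the data had been seen. Without 1 library, 5 HOXA and 2 to 4 HOXB genes were higher in FA, and 3 to 4 neuronal markers were lower. Developmental transcription factors were lower in 1 to 6 cases, secreted signals in 1 to 2 and extracellular matrix genes in 1 to 2. Heat shock genes were higher in 2 to 4 cases, p53 target genes in 0 to 4, mitotic genes in 1 to 5, oxidative phosphorylation genes in 13 to 24 and ribosomal protein genes in 18 to 51. With window medians removed, 2 HOXA, 0 HOXD, 12 oxidative phosphorylation and 19 ribosomal protein genes were higher; HOXA9 and HOXA5 were among those lost (adjusted p = 0.111 and 0.0522).

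Between FA and EV 1263 genes were called, 8.17%, 760 higher and 503 lower, of which 34 and 63 changed by 2-fold or more; the groups' libraries did not overlap for 30.2% of genes, where chance gives 10%. This count rests on every library of the contrast: it was 654, 640 and 687 without EV replicates 1, 2 and 3, and 694, 737 and 765 without FA replicates 1, 2 and 3. It was 771 with window medians removed. Under TPM the split turned to 443 higher and 799 lower. The median of ribosomal protein genes was 0.056 under TPM and 0.017 with quantile normalization, and that of oxidative phosphorylation genes 0.084 and 0.069. None of the 11 called lists held with an estimated correlation. The fry test called 19 lists, all 11 among them.

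**Figure D3:**
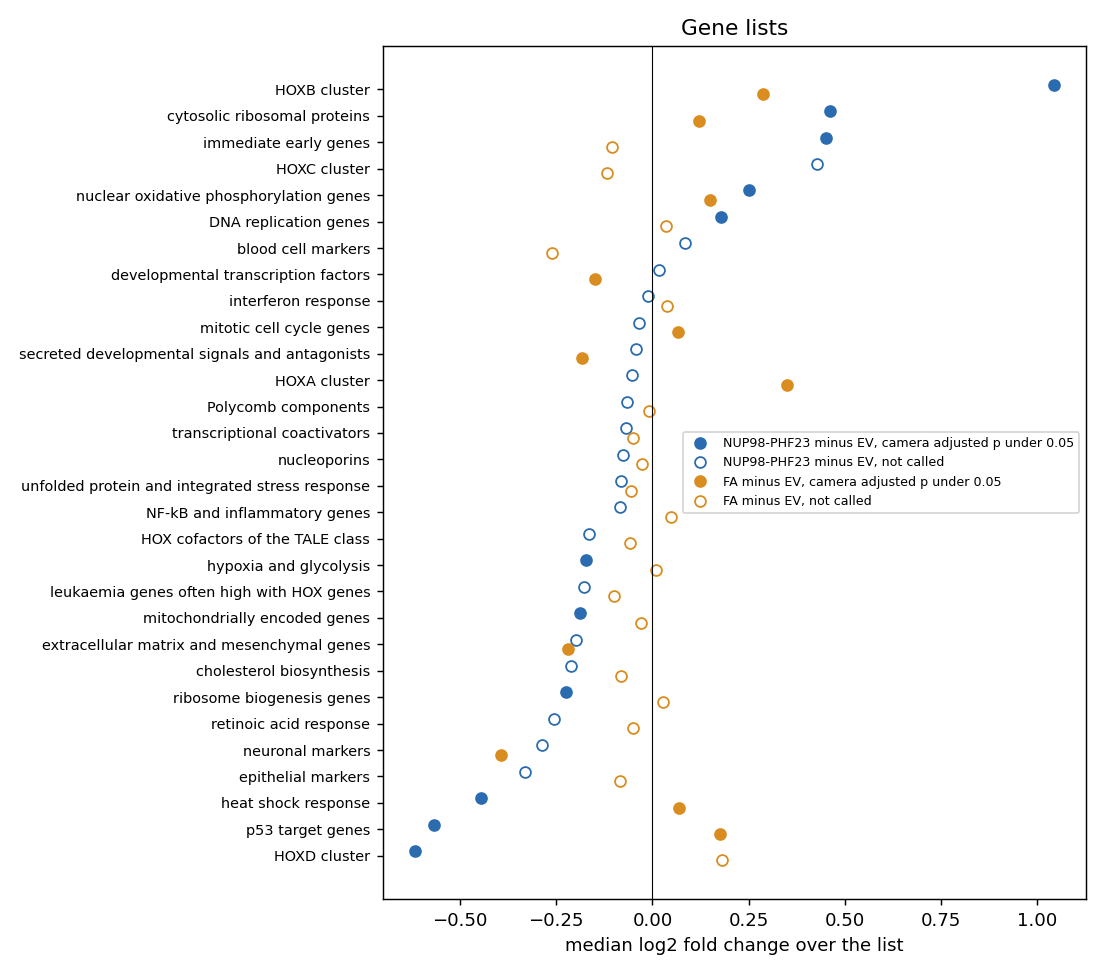
Median log2 fold change against EV (horizontal axis) over the tested genes of each of 30 gene lists, for NUP98-PHF23 (blue) and FA (orange), with filled points for a camera adjusted p under 0.05. HOXB genes had the highest median in NUP98-PHF23 at 1.04; heat shock and p53 target genes lay at -0.45 and -0.57 there and at 0.07 and 0.18 in FA.

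The intact and FA fusions were compared directly to test which responses differ with the repeats' phenylalanines. Of the 13 genes that went from under 0.5 FPKM in every EV library to 5 or more in every NUP98-PHF23 library, 12 were also under 0.5 FPKM in every FA library; the exception was TMSB4XP6, at 25.3 ± 24.1. CASKIN1 reached 11.7 ± 5.23 FPKM in FA. Among the genes with the largest rises, KISS1R stood at 0.0770 ± 0.0767 FPKM in FA, NGFR at 0.201 ± 0.0357, NOTUM at 0.158 ± 0.109, HES7 at 2.10 ± 0.204 and PRAC1 at 0.129 ± 0.224, with log2 differences of 6.63 ± 0.10, 4.91 ± 0.08, 4.68 ± 0.15, 4.17 ± 0.13 and 4.57 ± 0.14 in NUP98-PHF23 minus FA. AC005256.1 was listed at 0 in all FA libraries. ATP1B2, a sodium pump subunit, stood at 33.9 ± 2.43 against 1.19 ± 0.561 FPKM. Lower in the intact line were MAP7D2, at 0.420 ± 0.203 against 15.7 ± 0.863 FPKM (-3.56 ± 0.11), the neuropeptide gene NMU, at 4.27 ± 1.99 against 48.7 ± 1.55 (-3.32 ± 0.32), and Z98256.1 (-3.29 ± 0.28).

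CTD-2319I12.1 and RP11-68I3.2, higher, and RP11-150O12.1 and RP11-475I24.3, lower, completed the named noncoding genes. The histone gene HIST2H2AA3, higher, and TSSC2, MIR3665 and SNORA64, lower, were named as well, but are duplicated or very short and therefore uncertain. SNORA71A and RP11-76H14.2 lost their call without single libraries, with adjusted p up to 0.106 and 0.166.

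Of 17 heat shock genes 16 were lower in NUP98-PHF23 than in FA and 0 higher (16 and 1 over the list alone; median -0.50, camera adjusted p = 9.78e-10, and adjusted p = 0.01705 with an estimated correlation). Of 24 p53 target genes 17 were lower and 2 higher (18 and 2 over the list alone; median -0.63, adjusted p = 4.94e-06, and adjusted p = 0.01705 with an estimated correlation), and of 35 ribosome biogenesis genes 21 were lower and 0 higher (26 over the list alone; median -0.24, adjusted p = 2.46e-08, and adjusted p = 0.01705 with an estimated correlation). Another 7 lists lost their call in camera with an estimated correlation, at the camera adjusted p given after "then" for each. HOXB genes were higher in 7 of 9 cases (8 over the list alone; adjusted p = 0.000102, then adjusted p = 0.0708) and HOXD genes lower in 5 of 7 (5 over the list alone; 0.00354, then adjusted p = 0.0708). HOXA genes were lower in 6 and higher in 1 of 11 cases on either adjustment (0.0251, then adjusted p = 0.135, and 0.0638 with window medians removed), HOXA9 by a log2 difference of -1.11 ± 0.05. Ribosomal protein genes were higher in 66 and lower in 5 of 76 cases (67 and 6 over the list alone; 6.54e-22, then adjusted p = 0.281). Immediate early genes were higher in 12 and lower in 6 of 22 cases (14 and 6 over the list alone; 0.00301, then adjusted p = 0.0693), with MYC 0.91 ± 0.05 higher. Hypoxia and glycolysis genes were lower in 17 and higher in 5 of 32 cases (18 and 5 over the list alone; 0.0141, then adjusted p = 0.152, and 0.0672 with window medians removed). Mitochondrially encoded genes were lower in 8 and higher in 1 of 13 cases on either adjustment (0.0382, then adjusted p = 0.697, and 0.0507 with fry).

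Between the 2 fusions 6115 genes were called, 3150 higher in NUP98-PHF23 and 2965 lower, with 567 and 351 by 2-fold or more; libraries did not overlap for 51.1% of genes, where chance gives 10%. Under TPM the split turned to 2304 higher and 4057 lower. Members of 2 lists were also counted without single libraries, after the data had been seen. Immediate early genes were then higher in 11 to 13 cases and lower in 3 to 5. Ribosomal protein genes were higher in 66 to 68 cases and lower in 3 to 7. With window medians removed, 67 ribosomal protein genes were higher and 2 lower. Of the 10 called lists 3 held with an estimated correlation, and fry called 22 lists, 9 of the 10 among them.

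Of the 5999 genes called between NUP98-PHF23 and EV, 4538 also differed from FA in the same direction, 2414 of the higher genes (77.2%) and 2124 of the lower (74.0%). Independent lists of these sizes would share 637 and 551. Both contrasts use the same NUP98-PHF23 libraries, so a gene that differs in these libraries alone belongs in both. FA was called against EV in the same direction for 571 of the 5999 genes and in the opposite direction for 244. Independent lists would share 247 in the same direction, 154 higher and 93.5 lower, and 243 in opposite directions. In 20 simulations of unchanged groups with the same shared libraries both overlaps, with FA against EV and with the direct contrast, were 0. This follows from their having almost no calls and sets no bound where effects exist. Among the 486 genes higher by 2-fold or more with the intact fusion, whose median log2 fold change was 1.29, the median in FA was 0.01. Among the 436 lowered, with a median of -1.32, it was -0.27. Across genes, which are not independent replicates, the 2 fold changes against EV had a Pearson r of 0.321, against 0.496 on average in simulations without effects, and a covariance of 0.0730 against 0.0346, a difference of 0.0384. With separate EV libraries for the 2 contrasts, 1 for the one and 2 for the other, r was 0.0994 to 0.128 and the covariance 0.0296 to 0.0342. Part of the overlap of calls may come from the shared controls.

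**Figure D4:**
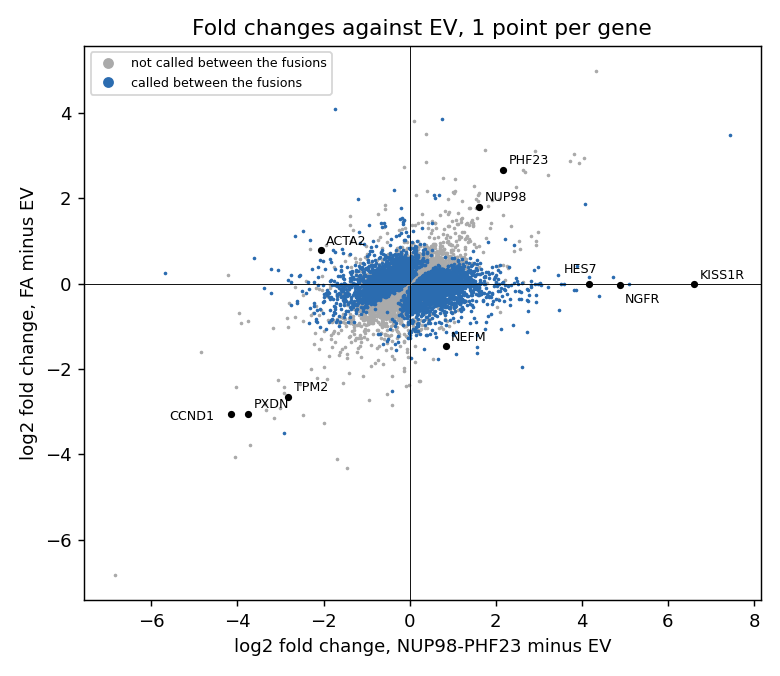
Log2 fold change against EV in NUP98-PHF23 (horizontal axis) and in FA (vertical axis), 1 point per tested gene, with blue points for genes called between the fusions and black points with names for single genes. KISS1R, NGFR and HES7 lie far to the right near the horizontal axis, at 6.62, 4.88 and 4.16, while CCND1, PXDN and TPM2 were low in both lines.

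Fold changes followed chromosomes in places. In FA against EV, the median log2 fold change of the 335 chromosome 8 genes with a mean FPKM of 5 or more was 0.34, and 147 of 450 tested chromosome 8 genes, 32.7%, were called higher, against 4.53% of other genes with a position. All 12 windows of 10 Mb on chromosome 8 that held at least 15 such genes had medians above 0, from 0.24 to 0.47, in FA against EV. The window from 30 to 40 Mb of chromosome 16, where ALDOA lies, had a median of -0.55 in FA. In FA the windows from 10 to 20 and 30 to 40 Mb of chromosome 11 and from 0 to 10 Mb of chromosome 5 had medians of 0.30, 0.30 and 0.27. In NUP98-PHF23 against EV the windows from 0 to 10 Mb of chromosome 20 and from 130 to 140 and 150 to 160 Mb of chromosome X had medians of -0.74, -0.43 and -0.53. Those from 50 to 60 Mb of chromosome 14 and from 20 to 30 and 80 to 90 Mb of chromosome 17 had medians of 0.32, 0.27 and 0.31. These windows, past 0.25 in either direction, and that limit were chosen after the data had been seen. In NUP98-PHF23 against EV, chromosome 17 as a whole had a median of 0.15, with 307 tested genes called higher and 91 lower. Chromosomes 14, 15 and 16 had medians of 0.106, 0.136 and 0.0839, with 115, 133 and 172 called higher and 58, 57 and 92 lower. Chromosome X had a median of -0.154, with 76 called higher and 162 lower, and chromosome 9 one of -0.0867, with 82 and 142. These chromosomes were picked in the same way. The window from 40 to 50 Mb of chromosome 17, where the HOXB genes lie, had a median of 0.19. With window medians removed, 9 HOXB genes were still called higher there.

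**Figure D5:**
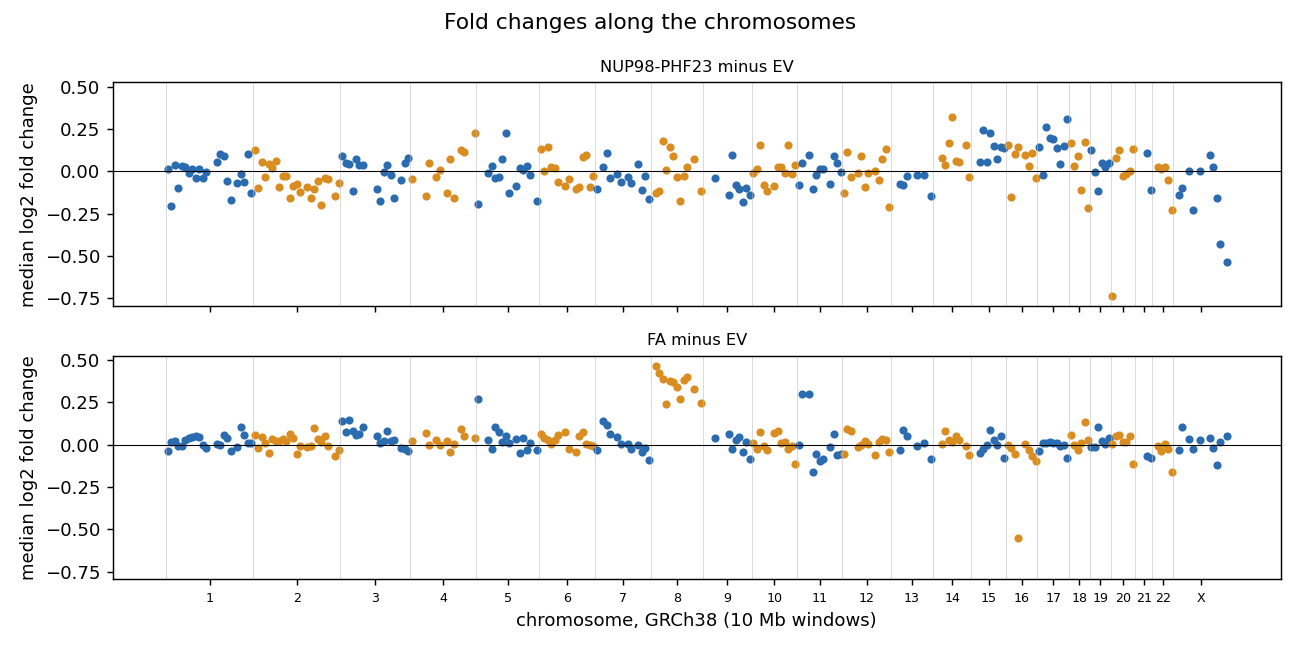
Median log2 fold change of genes with a mean FPKM of 5 or more in 10 Mb windows holding at least 15 such genes (points), along chromosomes 1 to 22 and X of GRCh38 (horizontal axis, alternating colours), for NUP98-PHF23 (top) and FA (bottom) against EV. Chromosome 8 stands above 0 in FA, at 0.24 to 0.47, and single windows of chromosomes 16, 20 and X lie at -0.55, -0.74 and -0.53.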

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

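The fold of 1.5 that sets apart 36 of the genes below and the count of list members without single libraries were chosen after the result was seen; the lists, the contrasts and the other tests were not.

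Against EV, 244 genes were called in opposite directions in the 2 fusion lines, 108 higher and 136 lower with intact NUP98-PHF23, about as many as the 243 that independent lists of these sizes would give. Of these, 36 changed by 1.5-fold or more in both. The homeobox gene LHX1 went from 1.80 ± 0.762 FPKM in EV to 13.5 ± 2.15 with the intact fusion and 0.408 ± 0.230 with FA, METRNL from 13.2 ± 0.840 to 47.3 ± 3.72 and 6.65 ± 0.694, and SYTL5 from 2.77 ± 0.236 to 11.7 ± 0.119 and 0.812 ± 0.0638. In the other direction IFI30, a lysosomal thiol reductase gene, went from 49.0 ± 2.34 to 13.6 ± 1.04 and 85.0 ± 5.63 FPKM, the smooth muscle actin gene ACTA2 from 8.09 ± 1.92 to 1.15 ± 0.113 and 14.5 ± 1.45 (its rise in FA was lost in 5 alternatives, at adjusted p up to 0.0887), and NELL2 from 16.0 ± 2.13 to 6.59 ± 1.40 and 38.5 ± 5.79.

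Heat shock genes and p53 target genes were called lower than EV with the intact fusion and higher than EV with FA, and their medians in NUP98-PHF23 minus FA were -0.4999 and -0.6313. In FA only 3 of 17 heat shock genes and 2 of 24 p53 target genes were called higher, with list medians of 0.07 and 0.18. The heat shock median was 0.0021 under TPM, and that list's call was lost with quantile normalization (camera adjusted p = 0.345). Both list results in FA were lost in camera with an estimated correlation, at adjusted p = 0.125 and 0.0872. When single libraries were left out, 0 to 4 of 24 p53 target genes were called higher in FA. The cause was not tested.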

How the results depend on the processing

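The fits without chromosome 8, with window medians, length or GC trends removed, and without genes shorter than 300 bases were chosen after the result was seen; the other alternatives were not.

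Counts of called genes were 5999 for NUP98-PHF23 against EV, 1263 for FA against EV and 6115 between the fusions, and 4538 genes called against EV also differed from FA. Leaving out 1 library gave 5074 to 5920, 640 to 1262, 5212 to 5893 and 3912 to 4102. A 2-fold minimum lowered the counts to 922, 97, 918 and 586. The count for FA against EV was 823 with the replicate block, although libraries of the same number were no more alike across groups (r -0.0945 to 0.0240) than others (-0.0624 to 0.0723), and 771 with window medians removed. The cause was not tested. The remaining alternatives stayed within 1.5-fold, including 5834, 1007 and 5852 without chromosome 8. The correlation of the fold changes against EV, 0.321, ranged from 0.287 to 0.375 without single libraries and from 0.304 to 0.337 otherwise.

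Of 10422 alternative values for named genes 9881 kept their call, 467 lost it, 63 gained one and 11 changed sign. All 11 arose with window medians removed. Against EV with the intact fusion these were NSDHL at 0.029, NOP56 at 0.0091 and DKC1 at 0.135; with FA, LDHA at -0.066, FDFT1 at -0.045 and MCM4 at -0.113. In NUP98-PHF23 minus FA they were SETD1A at -0.027, PCNA at 0.257, NOP56 at 0.093, DKC1 at 0.104 and RPL10 at 0.018. Each lies in a window whose genes had moved together. Of 720 alternative list results 643 kept their call, 45 lost it, 32 gained one and 0 changed direction.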

Other observations

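Some genes changed in the same direction with both forms of the fusion, though not all by the same amount. Beyond CCND1, PXDN, UNCX, BACE2, TPM2 and MGST1, the actin-bundling gene FSCN1 fell from 127.8 ± 0.780 FPKM in EV to 40.0 ± 0.0952 with the intact fusion and 63.5 ± 4.21 with FA. LINGO1 fell from 10.98 ± 0.814 to 4.42 ± 0.0240 and 3.95 ± 0.567 FPKM, and the transcription factor gene IRF8 from 3.98 ± 0.942 to 0.768 ± 0.405 and 0.765 ± 0.107. SLC12A5, a potassium-chloride cotransporter gene, rose from 2.46 ± 1.04 to 8.31 ± 2.75 and 8.61 ± 2.34, and PLEKHA6 from 0.417 ± 0.385 to 2.36 ± 0.347 and 1.87 ± 0.0227. By 2-fold or more, 26 genes were lower and 10 higher in both lines, NUP98 and PHF23 among the latter. These counts include F8A2 and F8A3, whose reads cannot be told apart securely. They also include NPM2, AC004383.3 and RPS20P10, whose calls in FA were lost in some alternatives.

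Lists without a call in a contrast are given here with the median log2 fold change and the camera adjusted p. With the intact fusion against EV these were HOXC genes (0.43, 0.254), TALE-class HOX cofactors (-0.16, 0.449), leukaemia genes often high with HOX genes (-0.18, 0.331), retinoic acid response genes (-0.26, 0.117), nucleoporins (-0.08, 0.117), coactivators (-0.07, 0.871), Polycomb components (-0.07, 0.871), unfolded protein and integrated stress genes (-0.08, 0.0882), interferon genes (-0.01, 0.310), cholesterol genes (-0.21, 0.226), extracellular matrix genes (-0.20, 0.249), epithelial (-0.33, 0.831), neuronal (-0.29, 0.651) and blood markers (0.09, 0.679). Developmental transcription factors (0.02, 0.831), secreted signals (-0.04, 0.679), NF-kB genes (-0.08, 0.919), mitotic genes (-0.03, 0.651) and HOXA genes (-0.05) had a mean of the other sign.

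With FA against EV the lists without a call were HOXC (-0.12) and HOXD genes (0.18), TALE cofactors (-0.06, 0.237), leukaemia genes (-0.10, 0.402), nucleoporins (-0.03, 0.6), coactivators (-0.05, 0.226), Polycomb components (-0.01, 0.808), unfolded protein genes (-0.06, 0.402), interferon genes (0.04, 0.525), immediate early genes (-0.10, 0.226), cholesterol genes (-0.08, 0.372), DNA replication genes (0.03, 0.233), ribosome biogenesis genes (0.03, 0.607), mitochondrially encoded genes (-0.03, 0.619) and blood markers (-0.26, 0.402). Retinoic acid genes (-0.05, 0.896), NF-kB genes (0.05, 0.711), hypoxia genes (0.01, 0.711) and epithelial markers (-0.09, 0.678) had a mean of the other sign.

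Between the fusions they were HOXC genes (0.23, 0.181), TALE cofactors (-0.20, 0.812), leukaemia genes (-0.20, 0.616), developmental transcription factors (0.10, 0.616), secreted signals (0.07, 0.305), retinoic acid genes (-0.22, 0.203), nucleoporins (-0.06, 0.188), unfolded protein genes (-0.12, 0.164), interferon genes (-0.24, 0.126), cholesterol genes (-0.12, 0.779), mitotic genes (-0.04, 0.635), DNA replication genes (0.12, 0.174), oxidative phosphorylation genes (0.07, 0.616), epithelial (-0.25, 0.786), neuronal (0.22, 0.356) and blood markers (0.47, 0.440). Coactivators (-0.01, 0.779), Polycomb components (-0.01, 0.812), NF-kB genes (-0.10, 0.812) and extracellular matrix genes (0.03, 0.812) had a mean of the other sign. Protocadherins, germline genes, and fibroblast and endothelial markers had too few tested genes for a list test, with medians of -0.00, -0.70 and -0.35 with the intact fusion and 0.39, -0.58 and -0.91 with FA, against EV.

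Every test of chromosome 8, and every removal of a length or GC trend, was chosen after the result was seen. So were the tests of translation factor genes, of another difference of the EV cells and of EV libraries left out in turn. The other tests below were not.

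Chromosome 8 genes were higher in FA than in EV in every measured window of the chromosome. Of those with a mean FPKM of 5 or more, 90.15% lay above 0, which extra copies of the chromosome in the FA cells could produce. The median was still 0.3159 after length and GC trends were removed, and all 3 FA libraries lay above every EV library, which argues against a length or GC trend and against 1 odd library. The spread of the changes was 1.262 times that on other autosomes, which leaves regulation gene by gene open. Copy number was not analysed here.

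Ribosomal protein genes were higher with the intact fusion than in EV, by a median of 0.4602. The median was 0.4261 with the length trend removed and 0.4438 with the GC trend removed, which argues against short transcripts or GC content as the source. It was 0.2793 under TPM and 0.1659 with quantile normalization, so the size of the rise depends on the scaling. Translation factor genes with the same 5' end motif and transcripts over 1500 bases, judged by the longest annotated transcript, also had a median of 0.361, so a response shared by such mRNAs could be involved. By the median transcript only 1 of these genes, EEF1A1, passes that length. Translation was not analysed here.

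Genes lower in both fusion lines numbered 220. When each EV library was left out in turn, 96 to 114 genes were called lower in both with the other 2, and at least 95.83% of these were lower in both lines than the library left out, against 31.6% to 31.7% of all genes, which argues against chance values of the EV libraries for those genes. Of the 26 lower by 2-fold or more in both, 20 were not called between the fusions, the uncertain F8A2, NPM2 and AC004383.3 among them. Such genes could answer to parts of the fusion other than the phenylalanines, or the EV cells could differ for another reason. The 3 groups do not separate these.

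Each real grouping of the samples was compared with all others of the same size. Of 10 groupings only 1, the real one, gave as many genes for each contrast, with 5999, 1263 and 6115 against at most 4, 3 and 2 in the others. For the 4538 genes that also differed from FA it was 1 of 20, with at most 677 in the others. Lists called numbered 11, 11 and 10 against at most 8, 6 and 7, again 1 of 10 each. Groupings that mix the groups thus still gave list calls in camera at the preset correlation, so such a call alone is weak evidence. With so few groupings the smallest possible shares are 0.1 and 0.05.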
